A study of Caenorhabditis elegans with 5 samples.

How the data were processed

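Young adult worms of the strains N2 and zim-2(tm574) were ground in liquid nitrogen and digested with micrococcal nuclease, and nucleosomes were precipitated with an antibody to H3K9me3, per the labels' protocols. Per the same protocols the N2 extract was fractionated on a 5 to 30% sucrose gradient, and the zim-2 extract was used without that step. GEO's labels gave 1 library for each of 5 groups. Files for 4 of them were used, and the N2 H3K4me2/3 library was not analysed here.

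The deposited alignment files hold, for each chromosome position and strand, a block of 147 bp and a number, taken here as the count of reads behind it. That the number is a count of reads was inferred from the values, which are whole numbers, and was not checked further. The deposited sequence files hold reads of 36 bases with no alignment or quality. The aligner, its settings, the treatment of reads with several matches and the genome build are not given in the sources used here. Coordinates are those of the alignment files, counted from 1, and only nuclear chromosomes were present in these files. The sequence files held 5472794 reads for N2 total nucleosomes, 5230214 for N2 H3K9me3, 7817802 for zim-2 total nucleosomes and 7721361 for zim-2 H3K9me3, of which 74.0%, 65.6%, 49.4% and 66.3% were counted in the alignment files. Distinct positions made up 91.7%, 78.7%, 94.0% and 89.2% of the aligned reads of these libraries, in the same order, so the N2 H3K9me3 library repeated positions most.

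Each read was placed at the middle of its nucleosome by a shift of 73 bp from its 5′ end and counted in windows and chromosome parts. Chromosome length was taken as the last aligned base in any library, and arms were the outer parts when each chromosome was cut into 3 of equal length. Pairing-centre ends were fixed from textbook genetics before the data were examined, as were the comparisons, the thresholds for enriched windows and the alternative settings listed first below. Counts were scaled to the aligned reads of the library. The 95% interval of a ratio of 2 counts was the exact conditional binomial (Clopper-Pearson) interval, and that of a ratio of 4 counts came from the logarithm of the ratio with the sum of reciprocal counts as its variance. All intervals cover counting error only and treat each read as independent. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow where positions repeat. With 1 library per group no p-value was computed.

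Enriched windows were windows of 1 kb with at least 20 total nucleosome reads in both strains and a ratio of at least 2. The regions named were the highest merged region of each chromosome, a rule fixed in advance; that they were ranked by the lower bound of the interval, the naming of the longest regions and of the deepest window, the limit of 1.5-fold for 10 kb windows of total nucleosomes, and the search ranges for distances were chosen after seeing the data. Core length was the most frequent opposite-strand distance between 140 and 160 bp, the shorter peak was sought between 110 and 130 bp, and repeat length was the maximum of the same-strand distances between 150 and 200 bp after smoothing over 11 bp, each relative to the median at 700 to 1000 bp. Reads that consisted of a tandem repeat with a unit of at most 15 bp over all 36 bases were counted from the sequence files, and 7 units other than single-base runs reached 200 reads over the 4 libraries.

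The alternatives tried were at most 1 read per position and strand, no shift, leaving out 10 kb windows whose total nucleosome count was over 3 times or under 1/3 of the median in either strain (211 of 10029 windows), arms as the outer 1/4 at each end, scaling to the median 10 kb window, a ratio of at least 3, windows of 5 kb, at least 50 total nucleosome reads, and overlap with a neighbouring window. Alternatives chosen after seeing the data were leaving out the deepest 10 kb window, taking as many top windows in zim-2 as in N2, and at most 10 reads per position and strand for distances. Work set in advance that needs a genome or gene annotation of the build of the files was not analysed here: enrichment of genes, of gene lists and of annotation classes, profiles around gene starts, GC content and reads over the zim-2 gene, so the strain labels were not checked against the targeted gene.

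The counting was tested on simulated Poisson counts without repeated reads, so the rates below do not cover the repeated positions of the real libraries. Only 3-fold and 5-fold changes were simulated, so the call rate near the limit of 2 is not known. With 86630 windows drawn from the real total nucleosome counts, 98 of 100 windows simulated at 3-fold were called for N2, and 0.108% of the windows with no change; for zim-2 all 98 were called at 3-fold, and 0.0511% with no change. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.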

Results

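Nucleosome cores of synchronized young adult Caenorhabditis elegans were released with micrococcal nuclease, which cuts the DNA between nucleosomes, and sequenced before and after precipitation with an antibody to histone H3 trimethylated at lysine 9 (H3K9me3), a mark of heterochromatin. The wild type strain N2 and the mutant zim-2(tm574) were studied; zim-2 encodes a zinc finger protein that acts at the pairing centre of chromosome V in meiosis. A total nucleosome library and an H3K9me3 library were analysed for each strain, 4 libraries in all, and an N2 library precipitated for H3K4me2/3 was not analysed here. Aligned reads numbered 4047737 for N2 total nucleosomes, 3431613 for N2 H3K9me3, 3863548 for zim-2 total nucleosomes and 5117172 for zim-2 H3K9me3. Each group held 1 library, so no difference below has a replicate check, no test across conditions was made, and intervals are 95% intervals that cover counting error only. Enrichment is the share of aligned H3K9me3 reads in a region divided by the share of aligned total nucleosome reads of the same strain.

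The first comparison asked where H3K9me3 lay along the N2 chromosomes, with each chromosome divided into a left arm, a centre and a right arm of equal length. H3K9me3 was higher on autosome arms than on autosome centres, with an arm-to-centre ratio of 1.695 (interval 1.690 to 1.701). The ratio was 1.94 on V, 1.65 on II, 1.34 on III and 1.27 on IV; on I it was 2.17, or 1.78 without a single 10 kb window at its right end. Chromosome X had the smallest contrast, 1.2 (interval 1.19 to 1.21). The centres were alike: enrichment lay between 0.683 on I and 0.776 on V. The highest values were those of the V right arm, 1.98 (interval 1.97 to 1.99), and the I right arm, 1.93 (interval 1.92 to 1.94), followed by the II left arm at 1.46 and the III left arm at 1.15.

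Part of the I right arm value came from a single 10 kb window, at 15060001 to 15070000 on I, close to the end of the chromosome. It held 113203 N2 H3K9me3 reads, 3.30% of that library, and 26214 N2 total nucleosome reads, 62.7 times the median window. Its enrichment was 5.09 (interval 5.03 to 5.16) in N2 and 2.56 (interval 2.51 to 2.62) in zim-2. The window also held 0.648% of the N2 total nucleosome reads and 0.297% of those in zim-2. Its background thus differed between the strains, and the enrichments do not compare H3K9me3 on an equal background. Without this window, a choice made after the data were seen, the enrichment of the I right arm was 1.52 in N2 and 1.30 in zim-2, and V had the highest N2 arm-to-centre ratio, 1.94, ahead of I at 1.78.

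**Figure D1:**
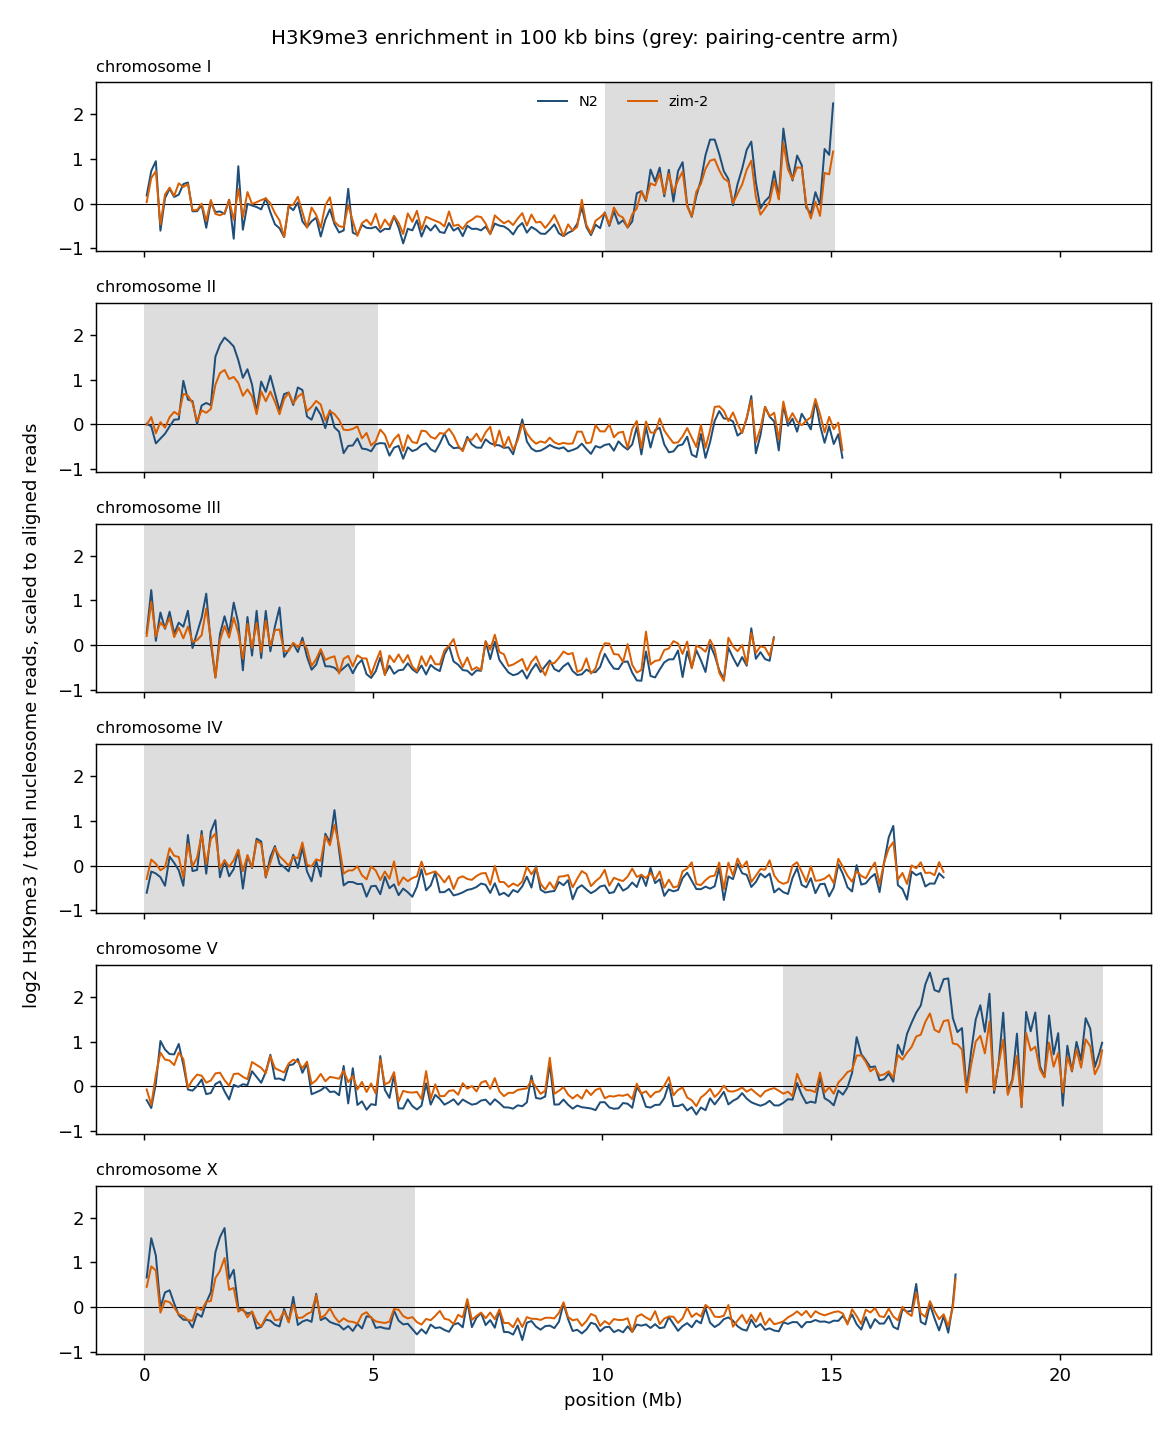
H3K9me3 enrichment (log2 ratio of H3K9me3 to total nucleosome reads, each scaled to its aligned reads) in 100 kb bins against position in Mb, one panel per chromosome, with N2 in blue, zim-2 in orange and the pairing-centre arm shaded grey. Both strains peak on V between 17 and 17.5 Mb, on II between 1.5 and 2 Mb and on X between 1.5 and 2 Mb, and the zim-2 peaks are lower.

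In N2 the highest 500 kb bin was at 17 to 17.5 Mb on V, with an enrichment of 4.95 (interval 4.88 to 5.03). The highest bin of II was at 1.5 to 2 Mb, at 3.43 (interval 3.38 to 3.49), and that of X also at 1.5 to 2 Mb, at 2.34 (interval 2.29 to 2.38). The highest bins of III, at 0 to 0.5 Mb, and of IV, at 4 to 4.5 Mb, reached 1.54 and 1.31. That of I, the short bin at its right end, was at 4.74, but 113203 of its 115867 H3K9me3 reads lay in the deepest window. In zim-2 the same bins were the highest of their chromosomes, at 2.25 on I, 2.66 on V, 2.11 on II, 1.58 on X, 1.44 on III and 1.30 on IV.

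The arms were then compared by pairing centre, the chromosome end at which homologues pair in meiosis, which lies on the right of I and V and on the left of II, III, IV and X. In N2 the arm with the pairing centre was more enriched than the opposite arm on each of the 6 chromosomes, by 1.91-fold on V, 1.64-fold on II, 1.51-fold on III, and 1.23-fold on both IV and X. On I the ratio was 2.10, or 1.61 without the deepest window. Over the autosomes the ratio was 1.724 (interval 1.717 to 1.730). The opposite arms still exceeded the centres, by 1.24-fold (interval 1.23 to 1.24). In zim-2 the pairing-centre arm was also the higher one on each of the 6 chromosomes, with ratios between 1.07 on X and 1.44 on I (1.35 without the deepest window) and an autosome ratio of 1.32 (interval 1.31 to 1.32).

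**Figure D2:**
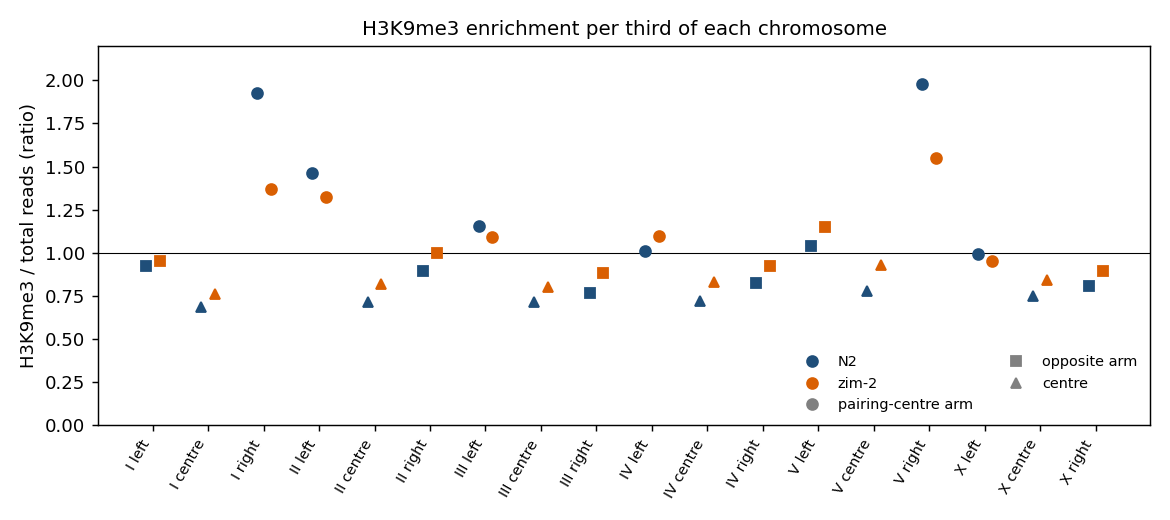
H3K9me3 enrichment (ratio of H3K9me3 to total nucleosome reads) of the left arm, centre and right arm of each chromosome, with N2 in blue and zim-2 in orange, circles for pairing-centre arms, squares for opposite arms and triangles for centres; bars are 95% counting intervals and are smaller than the symbols. The V right arm is the highest point in both strains, at 1.98 and 1.55, and every circle lies above the square of the same chromosome and strain.

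Chromosome X carried less H3K9me3 than the pooled autosomes, with an X-to-autosome ratio of 0.814 (interval 0.811 to 0.817) in N2 and 0.870 (interval 0.867 to 0.873) in zim-2. In N2 it was not below each autosome, with an enrichment of 0.844 against 0.839 on IV and 0.863 on III, while in zim-2, at 0.892, it was below each autosome, the nearest being III at 0.909. The difference lay in the arms. The centre of X was at 1.03 times the autosome centres in N2 (interval 1.02 to 1.04) and at 1.01 times in zim-2 (interval 0.999 to 1.01). The X left arm, at 0.992 in N2, exceeded the X right arm, at 0.807.

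Whether H3K9me3 is still enriched on the V pairing-centre arm in zim-2 mutants was the question the labels give for the mutant libraries. In zim-2 the V right arm had an enrichment of 1.55 (interval 1.54 to 1.56), the highest of the 18 chromosome parts, against 1.15 on the V left arm and 0.926 in the V centre. The value was below that of N2 by a ratio of 0.781 (interval 0.776 to 0.787). The zim-2 over N2 ratio was also below 1 on the I right arm, at 0.711, the II left arm, at 0.905, the III left arm, at 0.945, and the X left arm, at 0.961. Without the deepest window, the V right arm had the lowest ratio of the 18 parts, 0.764, followed by the I right arm at 0.855 and the II left arm at 0.885. With reads scaled to the aligned total, the other 13 parts had ratios above 1, up to 1.19 in the V centre. When each strain was scaled to its median 10 kb window instead, which shifted all ratios by -0.22 on the log2 scale, 1 part, the V centre at 1.03, stayed above 1, and the V right arm was at 0.671. The N2 extract had been fractionated on a sucrose gradient and the zim-2 extract had not, so strain and preparation cannot be told apart, and the ratios compare these libraries, not the conditions.

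At a finer scale, windows of 1 kb with at least 20 total nucleosome reads in both strains were examined, 86630 of 100270 windows. An enrichment of at least 2-fold was reached by 6473 windows in N2 (7.47%) and 4471 in zim-2 (5.16%), or by 10103 and 6413 when each strain was scaled to its median 10 kb window. Pairing-centre arms of autosomes, with 25.1% of the windows examined, held 73.7% of the enriched N2 windows and 72.4% of those in zim-2. The V right arm alone had 1913 enriched windows in N2, or 34.6% of its windows, and 1336 in zim-2, or 24.1%. In autosome centres the share was 0.713% in N2 and 0.460% in zim-2. On X, 322 of the 5308 windows of the left arm were enriched in N2 (6.07%), against 41 of 5748 in the centre.

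The windows of the strains overlapped. Of the 4471 zim-2 windows, 3592 (80.3%) were also enriched in N2, or 55.5% of the N2 windows. Independent lists of these sizes would share 334 windows, and lists independent within each of the 18 chromosome parts 895. In a test added after the data were seen, with as many top windows taken in zim-2 as in N2, 4476 of 6474 (69.1%) were shared. Across 1004 bins of 100 kb, log2 enrichment in the strains had a Pearson correlation of 0.95 and a Spearman correlation of 0.92, where bins are not independent replicates. Its SD over bins was 0.56 in N2 and 0.39 in zim-2.

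Adjacent enriched windows merged into 2442 regions in N2, with a median length of 1 kb, of which 103 were at least 10 kb long. Regions were called and ranked in N2, so the N2 values below were picked for being high and the zim-2 values were not. The region of V with the highest lower bound of its interval was at 17134001 to 17145000, with 3888 H3K9me3 and 471 total nucleosome reads in N2. Its enrichment was 9.74 in N2 (interval 8.85 to 10.7) and 4.92 in zim-2 (interval 4.48 to 5.41). On I the region ranked first was at 2057001 to 2060000, on the left arm, at 9.09 in N2 (lower bound 7.57) and 4.07 in zim-2 (interval 3.40 to 4.91). On II a single window at 14323001 to 14324000 on the right arm was at 9.13 in N2 (interval 6.49 to 13.2) and 4.22 in zim-2. The region of IV, 914001 to 921000, was at 7.13 in N2 and 4.02 in zim-2, that of X, 1764001 to 1775000, at 7.05 and 3.64, and that of III, 2117001 to 2119000, at 6.50 and 3.08. The longest N2 regions were 48 kb at 1721001 to 1769000 on II, with an enrichment of 4.21, and 48 kb at 17147001 to 17195000 on V, with an enrichment of 5.47. In zim-2 the longest region was 28 kb.

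Total nucleosomes were compared between the strains as the background of these ratios. Autosome arms were slightly lower in zim-2, at 0.968 of N2 (interval 0.966 to 0.970), and autosome centres slightly higher, at 1.039 (interval 1.036 to 1.041). The III left arm was at 0.924 and the I right arm at 0.909, or 0.969 without the deepest window; the III left arm, then at 0.921, was the lowest part. X was at 1.02 (interval 1.017 to 1.023). Of 9925 windows of 10 kb with at least 100 N2 reads, 3 were at least 1.5-fold higher in zim-2 and 110 at least 1.5-fold lower. All 110 of the lower windows were on chromosome arms, 42 of them on III. The higher windows were adjacent ones at 17350001 to 17360000 on IV, at 2.01 (interval 1.81 to 2.24), and at 17360001 to 17370000, at 1.79, and a window at 16690001 to 16700000 on V, at 1.73 (interval 1.52 to 1.97).

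**Figure D3:**
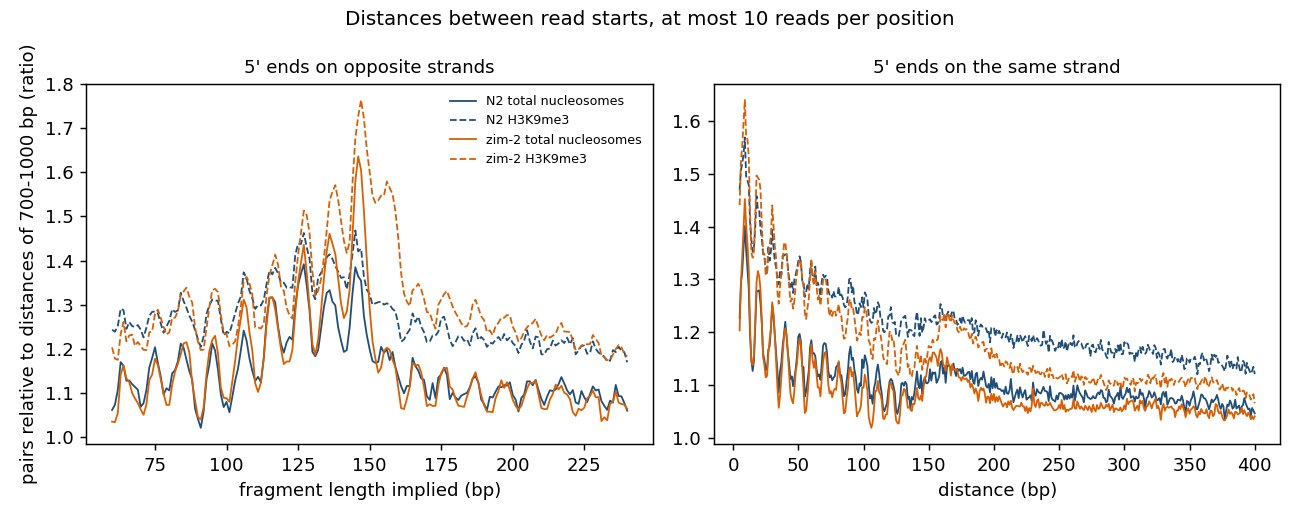
Number of pairs of read starts at each distance in bp, relative to distances of 700 to 1000 bp, with at most 10 reads per position; starts on opposite strands (left) give the length of the protected fragment, and starts on the same strand (right) the spacing of nucleosomes. N2 is in blue and zim-2 in orange, total nucleosomes as solid and H3K9me3 as dashed lines; a peak near 146 bp stands out in zim-2 and is no higher than the one at 127 bp in N2 total nucleosomes.

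The length of the protected core was read from the distance between read starts on opposite strands. Between 140 and 160 bp it peaked at 147 bp in N2 total nucleosomes, N2 H3K9me3 and zim-2 H3K9me3, and at 146 bp in zim-2 total nucleosomes. The range over chromosomes was 140 to 147 bp in both N2 libraries, where 140 bp is the edge of the search range, 146 to 147 bp in zim-2 total nucleosomes and 146 to 148 bp in zim-2 H3K9me3. With at most 1 read per position and strand both N2 libraries peaked at 145 bp. Shorter fragments, with a peak at 127 bp, were nearly as frequent in N2 total nucleosomes, at 1.62 times the background against 1.67 at the core peak. With at most 1 read per position and strand these heights were 1.336 and 1.330, so their order turned. In zim-2 total nucleosomes the heights were 1.47 and 1.69 with every read, and 1.37 and 1.55 with at most 1. Read starts on the same strand had maxima at 19, 30 and 40 bp in all 4 libraries when every read was counted. The maxima were sought in adjacent ranges of 10 bp, so their spacing does not measure a period. The broad same-strand maximum between 150 and 200 bp, taken as the nucleosome repeat length, was at 174 bp in N2 total nucleosomes (range over chromosomes 155 to 178) and 159 bp in N2 H3K9me3 (159 to 183). It was at 155 bp in zim-2 total nucleosomes (154 to 158), near the lower edge of the search range, and 160 bp in zim-2 H3K9me3 (159 to 167). The N2 values were thus not separable from those of zim-2 H3K9me3 at the spread between chromosomes. With at most 10 reads per position, the N2 total nucleosome curve was nearly flat, at 1.11 at 150 bp, 1.13 at 174 bp and 1.11 at 200 bp. Its maximum moved to 167 bp with at most 1 read per position and strand, so this repeat length is poorly determined. The curve of zim-2 total nucleosomes was at 1.15 at 150 bp, 1.16 at 155 bp and 1.08 at 200 bp. That of N2 H3K9me3 was at 1.22 at 150 bp, 1.25 at 159 bp and 1.21 at 200 bp. These maxima lie close to the core length and are weak, so they are not secure repeat lengths either.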

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

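All tests in this part were chosen after the result they measure had been seen.

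The sequence files hold reads that consist wholly of a short tandem repeat, a kind of read the comparisons of mapped regions did not use, and their place in the genome is not known here. Apart from runs of a single base, reads of the 9 bp unit ACCTAGACT were the most frequent, with 1508 in N2 total nucleosomes and 3909 in N2 H3K9me3. Per aligned read they were 3.06 times as frequent in H3K9me3 as in total nucleosomes in N2 (interval 2.88 to 3.25) and 2.69 times in zim-2 (interval 2.57 to 2.82). Per sequence read the order of the strains turned, with 2.71 in N2 and 3.61 in zim-2. The 15 bp unit AAGGGTCTCACCACG was at 4.94 in N2 and 2.99 in zim-2, from 16 and 24 total nucleosome reads. The 15 bp unit ACCACGATGGGTCTC was at 3.32 in N2 and 2.39 in zim-2, and per sequence read at 2.94 and 3.21. The 8 bp units ACATGCCT and AAGGATCT were at 2.18 and 1.71 in N2 and at 1.64 and 2.03 in zim-2. Reads of the 2 bp unit AG were at 1.43 in N2 and 1.41 in zim-2, and per sequence read at 1.27 and 1.89. No order of the strains is read from these units. All 6 units were picked out because they exceeded total nucleosomes in both strains by more than the counting interval.

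The ratio of H3K9me3 to total nucleosomes for reads of the telomere repeat TTAGGC lay on opposite sides of 1 in the strains. They were at 0.731 of their frequency in total nucleosomes in N2 (interval 0.642 to 0.831, 388 and 626 reads) and at 1.25 in zim-2 (interval 1.1 to 1.43, 609 and 367 reads). The H3K9me3 libraries were alike, at 113 in N2 and 119 in zim-2 per 1000000 aligned reads, while the total nucleosome libraries differed, at 155 and 95.0, a zim-2 over N2 ratio of 0.614 (interval 0.538 to 0.700). Each value rests on 1 library per antibody, and the difference between the strains was not tested. Per sequence read the ratios were 0.649 and 1.68. With scaling to the median 10 kb window they were 0.955 (interval 0.839 to 1.09) and 1.41, so the N2 value was then not separable from 1. Runs of A or of T over the whole read numbered 14751 in N2 total nucleosomes and 35 in zim-2 total nucleosomes. Whether the sequence files of the strains hold repeat reads to a like extent is therefore not known.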

How the results depend on the processing

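The alternatives that left out the deepest 10 kb window, took equal numbers of top windows, or allowed at most 10 reads per position were chosen after seeing the data. Of 71 values under alternatives, 28 stayed within the interval, the SD over chromosomes or 1.5 times the count, and 43 moved. The cause was not tested. A change of direction, to the other side of 1, was looked for only among the ratios, and 0 of them changed. Window counts and core and repeat lengths have no such direction. Omitting the shift moved no value beyond its interval. At depths near 43 reads per 1 kb window of N2 total nucleosomes, single windows are imprecise. Settings fixed in advance for genes, gene lists, annotation classes and GC strata were not run.

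With at most 1 read per position and strand, the arm-to-centre ratio was 1.54 in N2 and 1.31 in zim-2, the X-to-autosome ratio 0.864 and 0.896, and the ratio of pairing-centre to opposite arms 1.53 and 1.25. The zim-2 over N2 ratio of total nucleosomes was 0.972 on autosome arms, 1.035 in centres and 1.017 on X, and the zim-2 H3K9me3 repeat length was 166 bp. Without 10 kb windows of unusual input, the arm-to-centre ratio was 1.63 and 1.37, the X-to-autosome ratio 0.837 and 0.873, the pairing-centre ratio 1.62 and 1.30, the V right arm ratio of zim-2 over N2 0.764, and total nucleosomes 0.972 on arms, 1.03 in centres and 1.02 on X. With the outer 1/4 at each end as arms, the arm-to-centre ratio was 1.85 and 1.45, the pairing-centre ratio 1.90 and 1.39, and the V ratio 0.733. Without the deepest window these were 1.63 and 1.37, 1.62 and 1.30, and 0.764. Scaling to the median 10 kb window gave a V ratio of 0.671 and 10103 enriched N2 windows.

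A ratio of at least 3 left 3244 windows in N2 and 1032 in zim-2, 935 of them shared. With 5 kb windows there were 1482 and 899, 869 shared, and with at least 50 total nucleosome reads 1094 and 789, 710 shared; these settings test fewer or larger windows by construction. With at most 10 reads per position the repeat length was 164 bp in N2 total nucleosomes and 164 bp in zim-2 H3K9me3.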

Other observations

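The tests in this part were chosen after the results they bear on had been seen, apart from settings fixed in advance: 1 read per position, no shift, arms as the outer 1/4 and windows of unusual input left out.

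The gain of zim-2 total nucleosome reads near the right end of IV was delimited by 1 kb windows with a ratio of at least 1.5. A step at its edges follows from that rule. At 1 kb resolution it spanned 17 kb, from 17349001 to 17366000, with 869 reads in N2 and 1718 in zim-2, a ratio of 2.07 (interval 1.91 to 2.25). In the 20 kb to its left the ratio was 1.16 (interval 1.06 to 1.27), and in the 20 kb to its right 1.02 (interval 0.935 to 1.12). Read repeats do not account for it: with at most 1 read per position and strand the ratio was 1.95 (interval 1.79 to 2.13). Nor does a fault of the total nucleosome libraries alone, since H3K9me3 reads on the stretch were 2.75 times as frequent in zim-2 as in N2 (interval 2.52 to 3.00). Whether the zim-2 strain carries 2 copies of the stretch for each copy in N2 stays open. The total ratio of 2.07 is near 2, but the stretch and its edges were picked by that same ratio. The H3K9me3 ratio was 2.75, or 2.38 (interval 2.16 to 2.61) with at most 1 read per position and strand. Both exceed 2, but H3K9me3 reads were also at 1.06 and 1.12 in the 20 kb to the left and right. These values do not decide the copy number.

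The higher H3K9me3 on pairing-centre arms was set against technical causes. Repeated reads are not the whole cause, because with at most 1 read per position and strand the N2 ratio over the autosomes was 1.53 (interval 1.52 to 1.54), against 1.72 with all reads. Windows of abnormal copy number are not either, since the ratio was 1.62 without them. Low recovery of these arms among total nucleosomes is argued against by the H3K9me3 reads alone, which were 1.78 times as dense per base on pairing-centre arms, where total nucleosomes were 1.04 times as dense. Both densities are for the N2 autosomes and include the deepest window of I, which raises them. Under each alternative run for this ratio the pairing-centre arm was the higher in all 12 pairs of chromosome and strain. The cause was not tested further, and no biological explanation was tested.

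The lower enrichment of the V right arm in zim-2 was set against a lower contrast of the zim-2 libraries over the whole genome. A line of zim-2 on N2 enrichment, fitted to 927 bins of 100 kb outside that arm without windows of unusual input, had a slope of 0.577 and would put the arm at 1.61 in zim-2, where 1.55 was found from 2.05 in N2. The mean residual of the arm was -0.0672, inside the range of the other 17 chromosome parts, -0.0710 to 0.107, but close to its lower end. That end was the I centre, at 0.701 in N2. The X left arm, also a pairing-centre arm and at 1.07 in N2, had a residual of -0.0660, close to that of the V right arm. The I right and II left arms, at 1.51 and 1.53 in N2, had residuals of -0.0130 and 0.0287. In bins at 2 or more in N2, the median zim-2 over N2 ratio was 0.673 on the V right arm (28 bins) and 0.725 elsewhere (32 bins). Their mean N2 enrichment also differed, at 3.34 and 2.63. A lower contrast may account for most of the difference over the arm, and a further loss on V is not excluded. Fewer copies of the arm are argued against by total nucleosome reads, at 0.982 of N2. Strain and extract preparation cannot be told apart, because 0 zim-2 libraries came from gradient fractions.

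Sequence reads differed between the libraries in ways outside the comparisons. GC content was 38.7% in N2 total nucleosomes, 41.6% in N2 H3K9me3, 43.8% in zim-2 total nucleosomes and 41.6% in zim-2 H3K9me3. These values are over all sequence reads, of which 74.0%, 65.6%, 49.4% and 66.3% were aligned, in the same order; the origin of the unaligned reads is not known here, so the values describe the files and not the nucleosomes. The first base was A or T in 91.8%, 91.2%, 92.0% and 93.1% of reads, in the same order. Runs of A or of T over the whole read, counted together, made up 0.270% of N2 total nucleosome reads and 0.225% of N2 H3K9me3 reads. The zim-2 libraries had 35 and 26 such reads.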
